A study of Mus musculus with 2 samples.

How the data were processed

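The series measured DNase I accessibility in 2 libraries of cerebellum from male B6CASTF1/J mice aged 4 days, with 3 males named in the label of each library. Both libraries belong to 1 group, P4 cerebellum, and the labels number them as biological replicates 1 and 2. The labels of replicate 1 name 2 sequencing instruments, an Illumina NovaSeq and an Illumina HiSeq. The instrument of replicate 2 is not given in the sources used here. With 1 group, tests compare gene lists or sequences with random or control sets inside these libraries, and genes, peaks and footprints are not replicates.

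For each library the authors deposited peaks in narrowPeak format, called on the alignments of that library alone to the mouse assembly mm10, per the labels and the description files deposited with them. The peak value is the signal column of the deposited peak lists, which the authors normalised for depth by a factor that is not given in the sources used here. Every value was a whole multiple, within 0.05 steps, of a step of 0.00645 in replicate 1 and 0.00665 in replicate 2. The FDR files, with 8262092 and 21951038 intervals, hold the authors' false discovery rate of the cut rate (a q-value per short interval), and the deposited intervals are those under 0.05. Every peak of the less strict deposited list held an interval with an FDR under 0.05 and every peak of the stricter list one under 0.001. Footprints were deposited as positions whose value column is 0.01 on every line, so only positions were used. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. The description files were read but not used in any calculation.

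The depth in reads is unknown, because the files hold no read totals. If 1 step stands for 1 counted cut, the median peak of replicate 1 (0.787) rests on 122 cuts and that of replicate 2 (0.625) on 94, with exact 95% Poisson intervals of 0.654 to 0.94 and 0.505 to 0.765, and the weakest peaks on 6 and 8 cuts, with intervals of 0.0142 to 0.0842 and 0.023 to 0.105. These intervals cover counting error only.

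The less strict list was the main peak list. Peaks were shared when they overlapped by at least 1 bp, and the overlap was set against 100 random placements within the same chromosome. Genes came from GENCODE M21 on GRCm38 (mm10), with 21670 protein-coding genes of the autosomes and X. A gene had a promoter peak in a library when a peak overlapped the 500 bp on either side of any start of its protein-coding transcripts, and its value was that of the strongest such peak. Distal peaks were those of the library with fewer peaks that were shared and lay over 1000 bp from any protein-coding start, counted in the gene body and 50000 bp on either side.

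The 23 gene lists were fixed before the data were examined: granule cell progenitors and hedgehog response, early postmitotic granule neurons, mature granule neurons, Purkinje cells, GABAergic interneurons, unipolar brush cells and cerebellar nuclei, astrocytes and Bergmann glia, oligodendrocyte lineage, microglia and other myeloid cells, endothelial and mural cells, choroid plexus and ependyma, meninges and fibroblasts, red blood cell lineage, midbrain and hindbrain organiser, forebrain, Hox genes 1 to 5, Hox genes 6 to 13, liver, skeletal muscle, keratinocytes, housekeeping, cell cycle and immediate early genes. Of the genes listed, Ahsp was not found in the annotation by name and was not used. Tbr1 stands in both the forebrain and the unipolar brush cell and nuclei lists. The rule for named genes, fixed at the same time, took the first 4 genes of each list as ordered then and the member with the strongest promoter peak, by the mean over libraries of its percentile rank. It also took the 10 genes with the most distal peaks, the 5 strongest distal peaks, and the 6 called sequences with the highest and the 4 with the lowest odds ratio. Some genes that the rule selects are not named in the text. Other genes named in the text were chosen after their values were seen.

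Each list was compared with 10000 random lists of the same size, matched gene by gene on 10 classes of promoter CpG content (promoter peaks) or locus length (distal peaks). The p is two-sided, its smallest possible value is 0.0002, and it was adjusted over the 23 lists by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. A list that was not called was given no direction, and a call on the other side of the random median was taken as a reversal. The difference between the libraries was tested in the same way on the number of promoters gained and on the median log2 difference of values, tests that were chosen after seeing the data. The test of the log2 difference covered only the lists with at least 5 genes open in both libraries, and its p was adjusted over those lists. Consensus matches of 34 sequences on either strand were counted in 112281 and 261301 footprints extended by 5 bp on each side and in 102809 and 230195 control windows of equal width from the same peaks. These were compared by Fisher's exact test with 0.5 added to each cell of the odds ratio. A sequence was called when the adjusted p was under 0.05 in both libraries and the odds ratio was over 1.5, or under its inverse, in both.

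Packed weak peaks were compared with isolated ones in 10 classes of value, with an interval from 1000 bootstraps over stretches and isolated peaks, a test chosen after seeing the data.

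Alternative settings fixed together with the lists were the stricter peak list, a reciprocal overlap of 50%, equal numbers of the strongest peaks for the overlap, promoter windows of 200 and 2000 bp, only the 5'-most start, a peak in either library, no matching, a flank of 20000 bp, matching on both length and CpG content, only footprints inside peaks or shared by both libraries, no added flank, shuffled footprint sequence, covered bases in place of peak counts on X, and leaving out each replicate in turn. Alternatives chosen after seeing the data were peaks under a value of 0.4 left out, equal numbers of the strongest peaks for promoters, only footprints with a control window, and sequences with a CTCF match left out.

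The calculations were tested on simulated data. For promoter peaks, with 200 simulated lists of 16 genes per kind drawn from 21670 genes, 2.5% of unchanged and 96% of lowered lists had a p under 0.05. For distal peaks these shares were 1.5% of unchanged and 100% of raised lists, and for the gain of promoters between libraries 3% and 94.5%. The planted changes were large, and for the gain every promoter of a changed list was open in the second library. Simulated genes were independent, the p was not adjusted, and the matching classes were of gene length throughout. These shares are therefore not the power of the tests on the real lists. The overlap of 5000 intervals had 0 differences from bedtools. Among 20000 sequences, 100% of planted CTCF matches were found; of 33 other sequences 2 were also called, because they can lie inside the CTCF sequence, and 0 without planted sequences. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, pysam 0.24.0, matplotlib 3.10.9, bedtools 2.31.1 and samtools 1.23.1.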

Results

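DNase-seq maps open chromatin: the enzyme DNase I cuts accessible DNA, and sites with many cuts are called as peaks, while short protected gaps inside them are called as footprints. The series holds 2 libraries of the cerebellum of male B6CASTF1/J mice, a first-generation hybrid between a laboratory strain and the wild-derived CAST strain, taken at an age of 4 days, when granule cell progenitors are still dividing in the outer layer of the cerebellum. The labels name 3 males for each library and call the libraries biological replicates 1 and 2, so they form 1 group, and no comparison between conditions was possible. The data therefore answer which promoters and distal sites were open at this age, and how far the replicates differed. Peak values below are the authors' own normalised signal, n = 2 throughout, and the depth in reads is unknown because the deposited files hold no read totals. Over all genes with a promoter peak in both libraries, values were higher in replicate 2 by a median log2 difference of 1.02. The SD given for a gene includes this general difference between the libraries.

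Most listed promoters of the granule cell lineage, the most numerous neurons of the cerebellum, had a peak in both libraries, though no more often than matched random lists. Of the 16 genes of granule cell progenitors and the hedgehog response, 13 had a promoter peak in both libraries. They include Atoh1, the transcription factor that marks the progenitors (chromosome 6, 64729125 to 64731245), with a peak value of 0.540 ± 0.067 (SD, n = 2), and the hedgehog pathway genes Gli1 at 1.99 ± 0.469 and Ptch1 at 2.75 ± 1.57. Mycn, a driver of progenitor division, had values of 1.72 in replicate 1 and 5.49 in replicate 2, and Sox11 (chromosome 12, 27334264 to 27342574), the strongest of the list, had 2.27 and 11.4. Among 20 genes of early postmitotic granule neurons, 14 had a promoter peak in both libraries. Neurod1, a transcription factor of granule neuron differentiation, stood at 1.65 ± 0.244, Cntn2, an axonal adhesion molecule, at 1.68 ± 1.12, and Nfia, the strongest, at 4.49 ± 2.49 (SD, n = 2). Pax6 had a promoter peak in replicate 2 alone, at 3.66, whereas Zic1 was at 1.72 in replicate 1 and 0.705 in replicate 2. Of 16 mature granule neuron genes, 10 were open in both libraries: Cbln3 at 1.72 ± 0.394, Etv1 at 1.57 ± 0.442 and Tiam1 at 7.39 ± 4.87, while Gabra6 and Grin2c, receptor subunits of adult granule cells, had no promoter peak in either. The 3 lists did not differ from random lists matched on the CpG content of the promoter (two-sided permutation test, adjusted p = 1, 0.977 and 0.488). With the stricter peak list 9, 10 and 10 of their genes were open in both libraries (permutation adjusted p = 0.19, 0.49 and 0.98). No alternative setting called any of these lists.

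Purkinje cell genes were open at 15 of 20 promoters in both libraries. Calb1, a calcium-binding protein of these neurons, had 0.991 ± 0.170, Car8 0.826 ± 0.101, Rora 1.43 ± 0.439 and Itpr1, the highest by mean rank over the libraries, 5.60 ± 3.84 (SD, n = 2), and Pcp2 had no promoter peak in either library. GABAergic interneuron genes were open at 7 of 14. The GABA-synthesising enzyme gene Gad1 had 0.368 in replicate 1 and 1.12 in replicate 2, and Kit had 2.10 ± 0.226, whereas the lineage transcription factor genes Pax2, Ptf1a and Tfap2b had none in either library. Genes of unipolar brush cells and cerebellar nuclei were open at 4 of 12 promoters. Slc17a6, a vesicular glutamate transporter, had 0.903 ± 0.110 and Meis2 2.00 ± 1.22, Lmx1a and Tbr1 had a peak in replicate 2 alone, at 0.386 and 1.66, and Eomes had none. Purkinje genes did not differ from CpG-matched random lists (permutation adjusted p = 1), but GABAergic interneuron genes (random median 78.6%, permutation adjusted p = 0.0245) and those of unipolar brush cells and nuclei (random median 75%, permutation adjusted p = 0.0101) had promoter peaks less often. The permutation adjusted p of the GABAergic list ran from 0.00092 to 0.746 over 9 alternatives and was over 0.05 in 4 of them, a 2000 bp window, no matching, equal numbers of peaks and replicate 2 alone (without replicate 1, 0.144). That of the unipolar brush cell list ran from 0.00131 to 0.21 and was over 0.05 with a 2000 bp window, with no matching and without replicate 1 (permutation adjusted p = 0.121).

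Promoters of astrocyte and Bergmann glia genes separated the libraries. All 18 genes of astrocytes and Bergmann glia had a promoter peak in replicate 2, against 10 in replicate 1 and in both. Sox9, a glial transcription factor, had 2.04 in replicate 1 and 5.71 in replicate 2, and the glutamate transporter Slc1a3 had 0.603 ± 0.0687 (SD, n = 2), whereas Gfap at 0.419, Aqp4 at 0.492 and Gdf10 at 0.725 had a peak in replicate 2 alone. The gain of 8 genes exceeded that of CpG-matched random lists, the central 95% of which ran from -1 to 4 (permutation adjusted p = 0.00153), and with equal numbers of the strongest peaks it was 4, from 10 to 14 (permutation adjusted p = 0.0261). With replicate 2 alone the list was open more often than random lists (permutation adjusted p = 0.00153), with the stricter peak list less often (0.0299), and with both libraries it was not called (permutation adjusted p = 0.951, range over 9 alternatives 0.00153 to 1). Oligodendrocyte lineage genes were open at 8 of 16 promoters in both libraries (permutation adjusted p = 1), 8 in replicate 1 and 10 in replicate 2 (gain not called, permutation adjusted p = 1). The lineage factors Olig2 and Olig1 had 1.42 ± 0.471 and 1.30 ± 0.566 and the growth factor receptor gene Pdgfra 2.24 ± 0.771, and Sox10 had no promoter peak.

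Genes of blood, vessels, meninges and choroid plexus had peaks shared by both libraries at a minority of promoters. Counted by library, endothelial and mural genes were open in replicate 2 at 13 of 18 promoters, meningeal genes at 10 of 15 and choroid plexus and ependyma genes at 7 of 14, against 9, 6 and 6 in replicate 1 (gains not called, permutation adjusted p = 0.452, 0.239 and 1). With equal numbers of the strongest peaks the direction turned for endothelial (9 in replicate 1 and 5 in replicate 2) and meningeal genes (6 and 5), and 6 choroid plexus and ependyma genes were open in each (not called, permutation adjusted p = 0.0943, 1 and 1). Microglial and other myeloid genes were open at 2 of 17 promoters: Irf8 had 2.70 ± 1.36 (SD, n = 2), and Cx3cr1, Csf1r, P2ry12 and Spi1 had none. Of 13 red blood cell genes, Tal1 alone was open in both, at 0.635 ± 0.014, and Gata1, Klf1, Alas2 and Hbb-bt had no promoter peak in either library. Endothelial and mural genes were open at 8 of 18, with the glucose transporter Slc2a1 at 3.18 ± 1.61. Cldn5 and Cdh5 had 0.432 each in replicate 2 alone, Erg 0.271 in replicate 1 alone, and Pecam1 had none. Meningeal and fibroblast genes were open at 6 of 15, with Foxc1 at 0.712 ± 0.122 and Osr1 at 1.51 ± 0.515. The collagen genes Col1a1 and Col1a2 had 0.399 and 0.432 in replicate 2 alone, and Twist1 had none. Genes of choroid plexus and ependyma were open at 6 of 14, with Foxj1 at 7.35 ± 4.08 and Rsph1, the strongest, at 12.5 ± 7.64, and Ttr and Folr1 had none and Aqp1 had 0.672 in replicate 2 alone. With all peaks and CpG matching none of these 5 lists was called (permutation adjusted p = 0.325, 0.409, 0.414, 0.389 and 1, in the order above). Some alternatives called them open less often than random lists: no matching for microglia (permutation adjusted p = 0.00307) and red blood cells (0.00329), the stricter peak list for endothelial (0.024) and meningeal genes (0.00131). Equal numbers of peaks did so for red blood cells (permutation adjusted p = 0.0464), endothelial (0.00537) and meningeal genes (0.0393), and the 5'-most start for endothelial genes (0.0348). Over 9 alternatives the highest permutation adjusted p of these lists was 0.725 for microglia, 1 for red blood cells, 0.936 for endothelial and 0.991 for meningeal genes.

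Regional patterning genes had few promoters open in both libraries, and the forebrain and Hox 1 to 5 lists differed between them. In the midbrain and hindbrain organiser list, 2 of 10 genes were open in both libraries, En2 at 1.26 ± 0.288 and the signalling inhibitor gene Spry1 at 5.08 ± 1.65 (SD, n = 2). En1 had 0.718 in replicate 2 alone, Gbx2 1.26 in replicate 1 alone, and Fgf8 had no promoter peak. Forebrain genes were open in both libraries at 5 of 20 promoters, among them Emx2 at 0.929 and 2.87 and Bcl11b at 1.15 and 2.74 in replicates 1 and 2. Replicate 2 had promoter peaks at 17 forebrain genes and replicate 1 at 5, and Emx1 (1.41) and Six3 (0.698) were open in replicate 2 alone. Hox genes 1 to 5, which pattern the hindbrain, were open in both libraries at 5 of 15 promoters, in replicate 1 at 9 and in replicate 2 at 5. Hoxa4 (chromosome 6, 52189671 to 52191753) had 2.15 in replicate 1 and 0.679 in replicate 2, Hoxb5 had 1.95 and 1.56, Hoxa2 had 0.748 in replicate 1 alone, and Hoxa3 had none. Of 24 Hox genes 6 to 13, which pattern spinal cord and trunk, 2 were open in both, Hoxa7 at 2.29 ± 0.0451 being the stronger, while Hoxa6 and Hoxa9 had none and Hoxa10 had 1.26 in replicate 2 alone.

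Each of these 4 lists was open less often than CpG-matched random lists. The random medians were 80% for the organiser, 80% for the forebrain, 73.3% for Hox 1 to 5 and 83.3% for Hox 6 to 13. The permutation adjusted p was 0.00153 for the organiser, the forebrain and Hox 6 to 13, whose unadjusted 0.0002 is the smallest the random lists can give, and 0.0046 for Hox 1 to 5. The forebrain list was no longer called without replicate 1 (permutation adjusted p = 1, range 0.00092 to 1 over 9 alternatives), and the Hox 1 to 5 list was no longer called without replicate 2 (permutation adjusted p = 0.532) or without matching (0.169, range 0.00092 to 0.532). The organiser list lost its call without matching (permutation adjusted p = 0.059, range 0.00092 to 0.059). The difference between the libraries was itself tested: the forebrain list gained 12 promoters in replicate 2 where the central 95% of random lists ran from -1 to 4, and the Hox 1 to 5 list fell by 4 where it ran from -1 to 3 (permutation adjusted p = 0.00153 for both). In replicate 1 the random lists for the forebrain had a median of 80% of promoters open, against 25% for forebrain genes, so they had less room to gain. Many Hox genes are neighbours, whereas random lists are drawn from the whole genome. The p of both Hox lists may therefore be too small in each of these promoter tests. Among genes open in both libraries, the 5 Hox 1 to 5 promoters had a median log2 difference of -1.15 (replicate 2 minus replicate 1), where the central 95% of CpG-matched random lists ran from -0.18 to 1.05 (permutation adjusted p = 0.003). In the same test the 5 forebrain promoters, at 1.255, and the 10 astrocyte and Bergmann glia promoters, at 1.09, were not called (permutation adjusted p = 0.255 and 0.335). The median over all genes open in both libraries was 1.02.

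**Figure D1:**
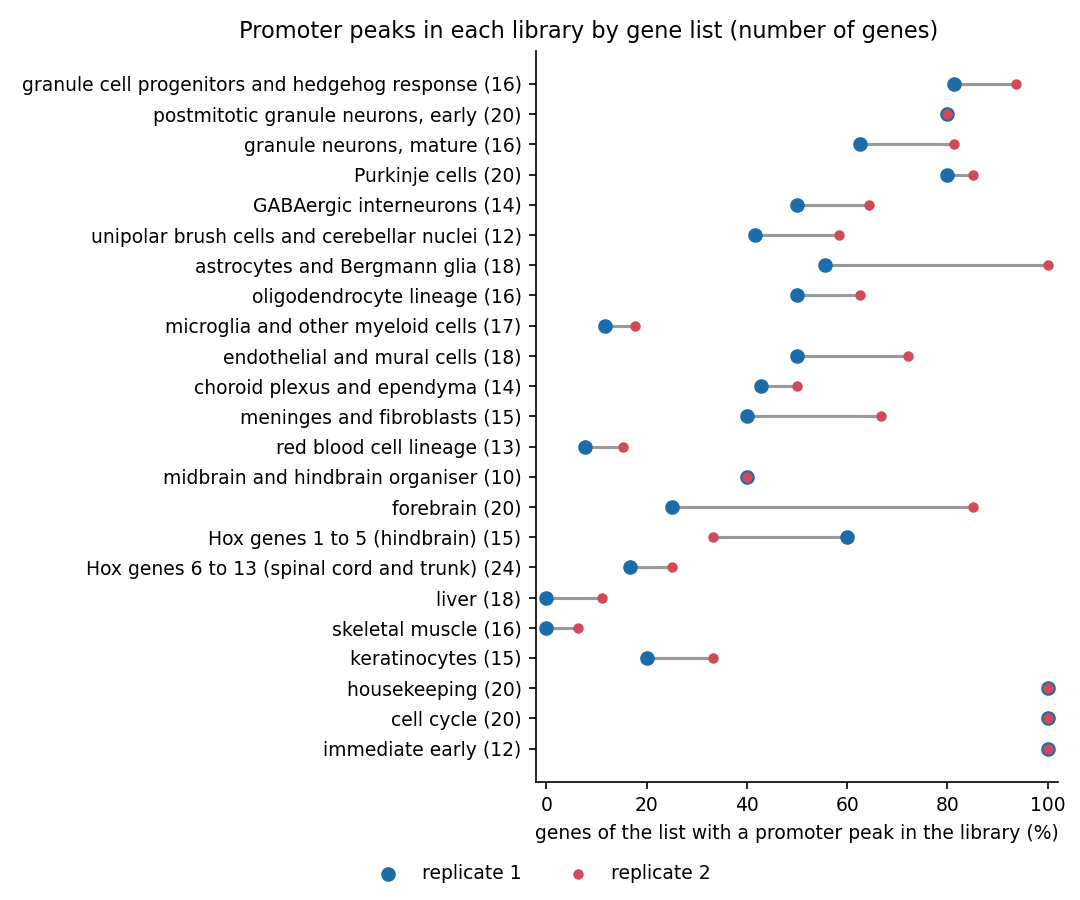
Percent of the genes of each of 23 lists with a promoter peak in replicate 1 (larger blue points) and in replicate 2 (smaller red points), with the number of genes of each list in brackets. Forebrain genes lie at 25% and 85%, astrocyte and Bergmann glia genes at 55.6% and 100%, and Hox genes 1 to 5 at 60% and 33.3%.

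Promoters of other organs were mostly closed and those of genes used by all cells were open. None of 18 liver genes, among them Alb, Apoa1 and Hnf4a, and none of 16 skeletal muscle genes, among them Myod1, Myog, Acta1 and Ckm, had a promoter peak in both libraries. Of 15 keratinocyte genes 3 did, with Krt10 at 2.57 ± 1.28 (SD, n = 2), and Krt5, Krt14 and Trp63 had none. All 20 housekeeping genes were open, Actb at 7.97 ± 5.37, Gapdh at 6.64 ± 4.89, Ppia at 8.94 ± 3.87, Tbp at 6.46 ± 3.18 and the ribosomal protein gene Rplp0 at 11.1 ± 4.91. So were all 20 cell cycle genes, with Mki67 at 3.36 ± 1.94, Top2a at 4.34 ± 2.43, Ccnb1 at 4.38 ± 1.95, Cdk1 at 5.04 ± 1.97 and Mcm5 at 9.28 ± 6.12. All 12 immediate early genes were open as well: Fos had 2.29 ± 0.670, Egr1 7.85 ± 4.97, Npas4 2.84 ± 2.51 and Arc 3.81 ± 2.62. Liver (random median 22.2%, permutation adjusted p = 0.0161) and muscle genes (25%, permutation adjusted p = 0.021) were open less often and housekeeping genes more often (85%, permutation adjusted p = 0.0213) than CpG-matched random lists. Keratinocyte, cell cycle and immediate early genes were not called (permutation adjusted p = 0.722, 0.375 and 0.0602), though without matching keratinocyte genes were open less often (permutation adjusted p = 0.0101), and cell cycle and immediate early genes more often (0.00092 and 0.0092), with highest values over 9 alternatives of 0.991, 0.921 and 0.725. The liver, muscle and housekeeping calls were lost with a 2000 bp window (permutation adjusted p = 0.555, 0.555 and 0.082) and with the 5'-most start (0.101, 0.101 and 0.114), liver and muscle with the stricter list (0.0682 and 0.0771), and liver and housekeeping without replicate 1 (0.129 and 0.139). The lowest value over 9 alternatives was a permutation adjusted p of 0.00092 for each of these 3 lists, and immediate early genes were called with equal numbers of peaks (0.0322).

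**Figure D2:**
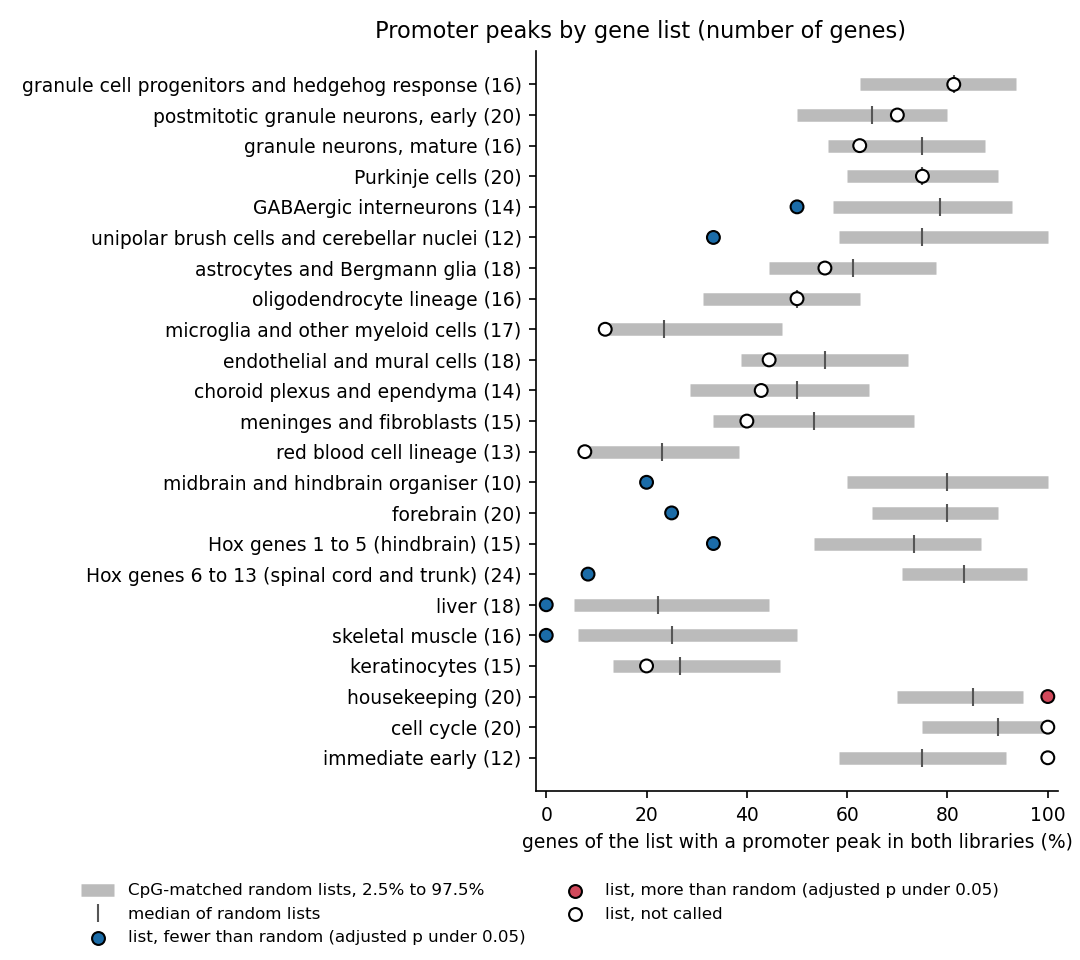
Percent of the genes of each list with a promoter peak in both libraries (points), beside the median and the central 95% of 10000 random lists matched on promoter CpG content (ticks and grey bars). Blue points, 8 lists, lie below and the red point, the housekeeping list, above the random lists at an adjusted p under 0.05; open points were not called.

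Over the genome, 12774 of 21670 protein-coding genes (58.9%) had a promoter peak in both libraries. Replicate 2 alone had a promoter peak at 1321 further genes, replicate 1 alone at 211, and 7364 had none in either. The share followed the CpG content of the promoter, from 3.97% in the lowest of 10 equal classes to 96.7% in the highest. Receptor families of the nose were closed: 6 of 1134 olfactory and 1 of 331 vomeronasal receptor genes had a promoter peak in both libraries.

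The libraries differed in the number and strength of their peaks, housekeeping promoters included. Replicate 1 had 61896 peaks covering 11.4 Mb (0.417% of the chromosomes) and replicate 2 had 131518 covering 24.7 Mb (0.906%), with a median width of 180 bp in each. Of the replicate 1 peaks, 44000 (71.1%) overlapped a replicate 2 peak, and of the replicate 2 peaks, 43955 (33.4%) overlapped a replicate 1 peak. Over 100 random placements the shares were 1.77% to 1.99% and 0.862% to 0.973%. The Jaccard index of covered bases was 0.259. Strong peaks were shared and weak ones were not: the shared percent rose from 1.78% in the weakest class of replicate 1 to 99.6% in the strongest, and from 4.25% to 97.8% in replicate 2. Across shared peaks, which are not independent replicates, the log values correlated with Pearson's r = 0.855 and Spearman's rho = 0.844. Values were higher in replicate 2 at 80.5% of shared peaks, by a median log2 difference of 0.63 (SD across peaks 0.71), and at all 20 housekeeping promoters, by a median of 1.31. With equal numbers of the strongest peaks 60.8% and 60.3% were shared.

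**Figure D3:**
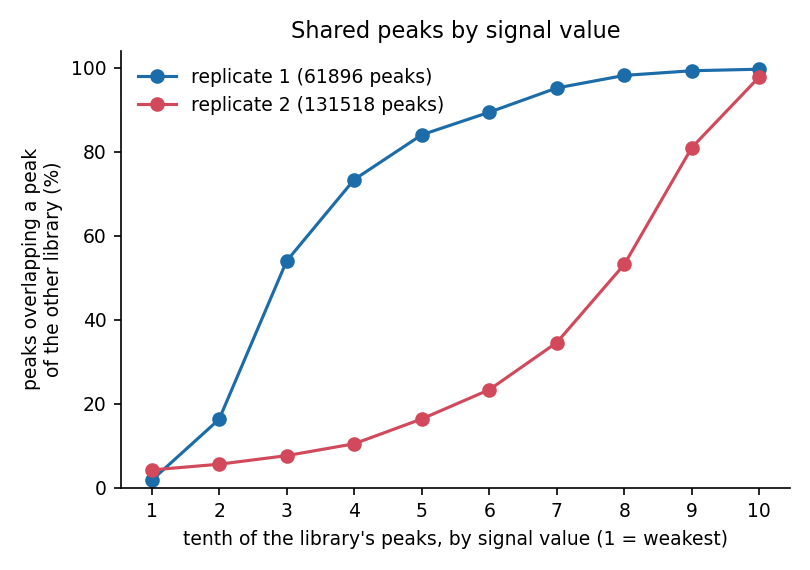
Percent of peaks overlapping a peak of the other library, by class of signal value (10 classes of equal size, 1 being the weakest), for replicate 1 (blue) and replicate 2 (red). Replicate 1 runs from 1.78% to 99.6% and replicate 2 from 4.25% to 97.8%.

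Away from promoters, 24109 peaks of replicate 1 were shared with replicate 2 and lay over 1000 bp from any protein-coding start. Among the genes with the most such peaks in their body and 50000 bp on either side were Gm20388, an annotation of 4435 kb on chromosome 8, with 134, the fibroblast growth factor receptor gene Fgfr2, annotated over 2961 kb, with 45, Gse1 with 33, Nfic, a nuclear factor I gene, with 31 and Celf5 with 30. Auts2 had 29, and Camta1, Gm21887 and Mid1 had 24 each. Gse1 lies within Gm20388, Celf5 next to Nfic and Gm21887 next to Mid1. The loci of these genes overlap, so their counts are not separate. Early granule neuron and immediate early genes had the highest median, 4 peaks per gene, followed by granule cell progenitor, mature granule neuron, astrocyte and oligodendrocyte genes at 3.5. Hox genes 6 to 13 and housekeeping genes had a median of 3, Purkinje, choroid plexus and organiser genes 2.5, and red blood cell genes 0. Microglial, endothelial, meningeal, forebrain, Hox 1 to 5, muscle, keratinocyte and cell cycle genes had a median of 2, GABAergic interneuron and unipolar brush cell genes 1.5, and liver genes 1.

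No list was called against random lists matched on locus length in the permutation test. The lowest permutation adjusted p was 0.0613, shared by the granule cell progenitor, early granule neuron, astrocyte, oligodendrocyte, Hox 6 to 13 and immediate early lists, and 7 lists had an unadjusted p under 0.05, the seventh being housekeeping (permutation adjusted p = 0.118). With a flank of 20000 bp the early granule neuron, astrocyte, Hox 6 to 13 and immediate early lists had more distal peaks than random lists (permutation adjusted p = 0.0115 for each), and the immediate early list also with the stricter peak list (0.0046). In replicate 2 alone the astrocyte (permutation adjusted p = 0.0215), oligodendrocyte (0.0115) and immediate early lists (0.0046) had more, and in replicate 1 alone the early granule neuron (0.0138), astrocyte (0.023), Hox 1 to 5, Hox 6 to 13 and immediate early lists (0.00153 each). Neighbouring Hox genes share distal peaks, so the p of both Hox lists is too small and these calls are not taken as a difference. Over 6 alternatives the highest permutation adjusted p was 0.14 for the immediate early list, 0.545 for early granule neurons, 0.681 for astrocytes and oligodendrocytes and 1 for both Hox lists.

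Of the 5 strongest shared distal peaks, 3 lay in exons. Their values were far above the 95th percentile of peak values, 3.46 in replicate 1 and 4.96 in replicate 2. Peaks were not filtered for repeated sequence or regions of artefact signal, so these values may not reflect accessibility in the tissue. The first, on chromosome 15 from 99735701 to 99736040, lay in an exon of Cers5, a ceramide synthase gene, with values of 54.4 in replicate 1 and 29.6 in replicate 2. The next, on chromosome 17 from 39846781 to 39846900, lay in an annotated ribosomal RNA gene, at 36.6 and 40.2. One on chromosome 9 from 123461921 to 123462080 lay in an exon of Lars2, the mitochondrial leucyl-tRNA synthetase gene, at 30.1 and 29.0. The last pair were intergenic: on chromosome X from 143482981 to 143483120, 35471 bp from Pak3, at 27.9 and 26.9, and on chromosome 6 from 49236441 to 49236620, 7304 bp from Tra2a, at 21.4 and 27.9.

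Footprints were richest in the sequence bound by CTCF, the insulator protein that anchors chromatin loops. A CTCF match was found in 3.33% of 112281 footprints of replicate 1 and 2.00% of 261301 of replicate 2, against 0.0204% and 0.0196% of control windows from the same peaks, odds ratios of 165 and 103. The full nuclear factor I site, bound by a family that includes Nfia, had odds ratios of 18 and 49.6, which rest on 29 and 84 matches in footprints and 1 in the controls of each library, NRF1 23.4 and 26.9, RFX, bound by regulators of ciliary genes, 12.4 and 14.2, REST, a repressor of neuronal genes, 11.9 and 5.46 (19 and 15 matches, 1 and 2 in controls), and CREB 8.09 and 5.96. Called more often as well were the SP/KLF, EGR, YY1, ZIC and ATOH1/NEUROD sequences, the last with odds ratios of 1.53 and 1.61. The homeodomain TAATTA sequence (0.609 and 0.661), the GATA sequence of blood regulators (0.530 and 0.467), the POU octamer (0.438 and 0.525) and the sequence of SPI1, a myeloid regulator (0.435 and 0.464), were found less often in footprints than in controls.

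Of 34 sequences 11 were called more often and 4 less often in both libraries (Fisher's exact test, two-sided, adjusted within a library). With sequences holding a CTCF match left out, a setting chosen after seeing the data because the CTCF sequence can contain the others, the ZIC odds ratios of 2.14 and 1.72 became 1.65 and 1.41 and those of ATOH1/NEUROD 1.30 and 1.5, and neither was called. REST lost its call in footprints shared by both libraries and with no added flank, POU with no added flank, TAATTA in shared footprints, and TAATTA and EGR against shuffled sequence. Against shuffled sequence POU was found more often, with a mean log2 odds ratio of 1.46, and SPI1 lost its call and turned direction, with odds ratios of 1.27 and 1.35, so the direction of both depends on the control.

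**Figure D4:**
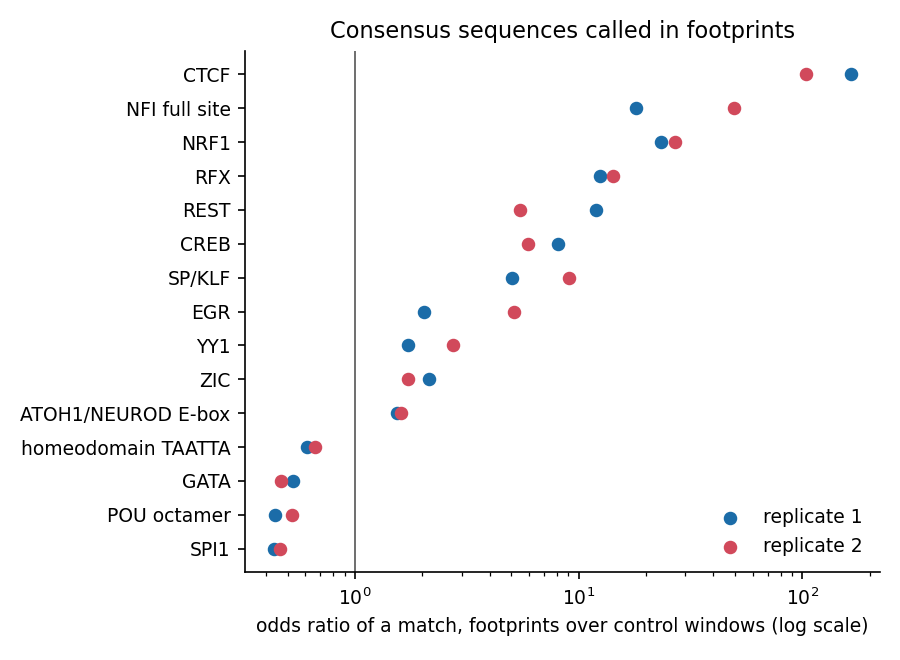
Odds ratio of a match in footprints over control windows (log axis) for the 15 sequences called in both libraries, in replicate 1 (blue) and replicate 2 (red). Values run from 165 and 103 for CTCF to 0.435 and 0.464 for SPI1, and the vertical line marks an odds ratio of 1.

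The footprints lay mostly inside peaks, 93.6% of them in replicate 1 and 91.6% in replicate 2, and 75.3% and 76.1% of peaks held at least 1. Within 500 bp of a protein-coding start lay 41.8% of the footprints of replicate 1 and 29.6% of those of replicate 2. A footprint of the other library overlapped 56.3% of those in replicate 1 and 23.4% of those in replicate 2.

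Chromosome X, of which males carry 1 copy, had fewer and weaker peaks than the autosomes. Its density was 9.89 peaks per Mb in replicate 1 and 22.4 in replicate 2, against 24.4 and 51.8 on the autosomes, ratios of 0.405 and 0.433. The lowest autosome, chromosome 3, had 18.9 and 43.0. The median value on X was 0.613 of the autosomal median in replicate 1 and 0.589 in replicate 2. Chromosome Y held 152 peaks in replicate 1 and 58 in replicate 2, with median values of 0.142 and 0.313, and 54 and 33 in the stricter list. Peaks were not filtered for repeated sequence, so these counts may not reflect accessibility in the tissue. The Y genes with a promoter peak, Ddx3y, Eif2s3y, Kdm5d and Uty, had one in both libraries, Ddx3y at 0.729 and 2.06.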

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

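Alternatives chosen only after seeing the data were those leaving out peaks under a value of 0.4, using equal numbers of peaks for promoters, keeping only footprints with a control window, and leaving out sequences with a CTCF match. Counts of open promoters moved little: the number of genes stayed between 11326 and 14306 in 9 alternatives. Of 207 values for single lists of promoters, 172 stayed on their side of the threshold, 13 gained a call, 21 lost one and 1 reversed. For distal peaks 125 of 138 stayed and 13 gained a call, and for motifs 207 of 237 stayed, 19 gained a call, 8 lost one and 3 reversed. The footprint counts stayed within 1.5 times. No paired analysis was possible because the libraries form 1 group. The depth in reads is unknown, so its effect on weak peaks could not be separated from the settings.

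With the stricter peak list there were 36611 and 79019 peaks in replicates 1 and 2, 75.4% and 34.9% of them shared, a Jaccard index of 0.273, r = 0.837 and rho = 0.834 across peaks, and an X to autosome ratio of 0.328 in replicate 1. A reciprocal overlap of 50% gave 56.8% and 26.7% shared, r = 0.852 and rho = 0.848. Equal numbers of peaks gave 60.8% and 60.3% with a Jaccard index of 0.362, and leaving out peaks under 0.4 gave 83.8% and 43.2% with 0.322. The reciprocal overlap changes the rule for sharing, and the other settings change which peaks enter.

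The number of lists open more often than random lists, 1 in the report, was 0 with a 2000 bp window, 3 with no matching, 0 with the 5'-most start and 2 with equal numbers of peaks. The number open less often, 8 in the report, was 4 with a 2000 bp window, and 4 to 7 when either replicate was left out. Astrocyte and Bergmann glia genes were open at 55.6% to 100% of promoters when either replicate was left out, the higher value coming from replicate 2 alone and reversing the direction. Lists with more distal peaks, 0 in the report, numbered 1 with the stricter list, 4 with a flank of 20000 bp and 3 to 5 when either replicate was left out, Hox lists with too small a p among them. Sequences called more often numbered 17 against shuffled sequence, and those called less often 7 in shared footprints, 7 with no added flank and 2 against shuffled sequence. Against shuffled sequence the mean log2 odds ratio reversed to 1.46 for POU, 0.39 for SPI1 and 0.66 for MEIS. Among sequences called in neither of these settings it also turned positive, for example for MEF2 (1.02), AP-1 (0.64) and TCF/LEF (0.60). Beyond what each setting changes by construction, the cause was not tested.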

Other observations

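In this part the tests of tissue from another region and of lower signal over background were fixed before their results were seen, and the other tests, as well as the genes and sequences named here, were chosen only after the results were seen.

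Single promoters also differed between the libraries. Among the genes with the highest promoter values in replicate 1 alone were the transcription factor genes Lhx1 (2.01), a gene of Purkinje cells, Pax5 (1.86) and Gbx2 (1.26), genes of the organiser, Irx5 (1.37), and Zic4 (1.20), a gene of granule neurons. Among the highest in replicate 2 alone were Slc4a7 (6.25), the potassium channel genes Kcnj9 (3.91) and Kcnh3 (3.31), Ddn (3.87), a gene of dendrites, Pax6 (3.66) and the muscarinic receptor gene Chrm1 (3.25). Among promoters open in both, Mab21l1 (1.56 and 0.572) and Irx2 (1.51 and 0.625) were higher in replicate 1, and Grin1 (0.858 and 4.72) in replicate 2. The highest value of either library, 177 in replicate 1 against 1.66 in replicate 2, lay at Gm10719 on chromosome 9 from 3017408 to 3021593. Beside it, Gm10717 (3.83 and 0.951), Gm10718 (1.43 and 0.259) and Gm10720 (1.02 and 0.186) were also higher in replicate 1. Peaks were not filtered for repeated sequence or artefact signal, so this stretch is not taken as a difference in promoter accessibility.

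Distal peaks found in 1 library alone, with a value of at least 0.4, numbered 4265 in replicate 1 and 45701 in replicate 2, with a GC content of 55.7% and 49.9%. A CTCF match was found in 1.01% of the peaks of replicate 1 alone and 3.77% of those of replicate 2 alone, an odds ratio of 3.8 that fell to 2.36 after matching on GC content, and a POU octamer in 0.633% and 1.97% (3.09, and 1.90 after matching). The odds ratio was higher for RFX (7.74, and 8.31 after matching) and MEF2 (3.94 and 2.68), which rest on few peaks of replicate 1 (0.0469% and 0.211%), and that of SP/KLF depended on the matching (1.12 and 2.30). Found less often in the peaks of replicate 2 alone were YY1 (0.914% and 0.392%; 0.422, and 0.366 after matching), GLI, the hedgehog effector (0.492% and 0.155%; 0.309 and 0.419), and ZIC (18.6% and 12%; 0.597 and 0.859). Each value sets 1 library against 1, and peaks are not independent, so these odds ratios are descriptions without a test.

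Replicate 2 had promoter peaks at 17 of 20 forebrain genes, such as Neurod6 (2.71) and Dlx5 (1.93), and replicate 1 at 5, while Hox genes 1 to 5 had 5 in replicate 2 and 9 in replicate 1; both labels say cerebellum and name no sort, and Tbr1 of the forebrain list also stands in that of unipolar brush cells and nuclei. With equal numbers of the strongest peaks forebrain promoters still went from 5 to 14 and Hox 1 to 5 promoters from 9 to 3 (permutation adjusted p = 0.0023 for both, and 0.00153 with all peaks). The difference therefore did not come from the number of peaks alone. A difference in peak calling sensitivity stays open, because the random lists were matched on CpG content only. In replicate 1 a median of 80% of their promoters was open, against 25% for forebrain genes, so they had less room to gain. Neighbouring Hox promoters are not independent, so the p of that list may be too small. Tissue of another brain region in the replicate 2 library may account for the difference between the libraries, but the test fixed in advance came out only in part: of distal peaks in 1 library alone, 91.8% in forebrain loci came from replicate 2, inside the central 95% of random lists of 75.7% to 98.2% (permutation p = 0.867), against 38.2% in Hox 1 to 5 loci (permutation p = 0.0016). Hox 6 to 13 loci, not part of that test, lay at 48.3% (permutation p = 0.0008), though promoters of that list went from 4 to 6. The explanation by other tissue stays open because a random median of 90.9% leaves little room above it, and because neighbouring Hox genes share peaks, so that their p is too small. These shares set 1 library against the other, so they also cannot tell which library holds such tissue. Tissue of another region in replicate 1 was not tested. Counting each peak once, Hox 1 to 5 loci held 11 in replicate 1 and 10 in replicate 2, and Hox 6 to 13 loci 10 and 6. With 1 group, no biological explanation was tested, and a different extent of dissection or a wrong label was not tested either.

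Replicate 1 had 61896 peaks and replicate 2 had 131518. The tables argue against a lower depth of replicate 1, provided that a step of the values means the same in both files, because the total implied by the step in replicate 2 was 0.97 of that in replicate 1, where 1.5 times as much was needed. A lower signal over background in replicate 1 may account for it: at 3801 shared distal peaks with a CTCF match, a class of sites open in most tissues, values were higher in replicate 2 by a median log2 difference of 0.52, over the 0.2 set in advance. The median was 0.63 at all shared peaks, 0.48 at distal peaks without such a match, 0.82 near starts and 1.31 at 20 housekeeping promoters, so the difference was not the same for every class. Since every class lay over 0.2, the result at CTCF peaks repeats the general shift of values. It does not single out a lower signal over background. No biological explanation was tested.

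In replicate 1, 7477 of 12390 weak peaks (value under 0.4) had at least 3 others within 10000 bp, in 624 stretches of up to 49.3 kb. This was a share of 60.3%, and in replicate 2 the share was 6.26%. Random placements over whole chromosomes reached at most 0.113% in replicate 1 and 0.399% in replicate 2. Such placements ignore where peaks can lie, so they argue only against an even scatter, in both libraries. Against weak accessibility common to both libraries as the whole cause, 3.09% of packed peaks were shared with replicate 2, where isolated ones weighted to the same values were shared 2.4 times as often (7.42%, 95% bootstrap interval of the ratio 1.88 to 3.14). The exceptions were the 3 weakest of 10 value classes, where 0% of isolated peaks were shared, and replicate 2, in that among its own weak peaks packed ones were shared more often (ratio 0.54). Local background of the peak calling around strong peaks may contribute and stays open: 6.57% of stretches had a strong peak within 5000 bp of an end, over the 3.53% that random placements reached, but under the 8.33% reached by placements near peaks. Accessibility in the tissue of replicate 1 alone was not tested and stays open, and 73.2% of packed against 6.55% of isolated weak peaks lay in peaks of the stricter list.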
